A study of Mus musculus with 7 samples.

How the data were processed

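Total RNA (400 ng per sample, column-purified) from 4 uninjured mouse digits and 3 blastemas, taken 2 weeks after amputation, was made into biotin-labelled cDNA with a whole-transcript kit and hybridised to 1-colour arrays, per the labels' protocols. The labels describe the samples of each group as separate biological replicates. They give no date, slide or other batch.

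The deposited values are on a log2 scale and were made with the R package oligo by RMA, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises probes into probe sets. Versions, settings and the array design are not given in the sources used here. The values run from 0.66 to 13.70, with array medians of 5.53 to 5.58, so a global difference in RNA content between groups would not show. The table holds 41345 probe sets and 0 columns of other samples. It carries no detection calls. In their place, the 95th percentile of the mean levels of 1105 olfactory receptor genes (5.52) served as a background proxy, chosen after the data were seen. Of the tested genes 13316 had a mean above it in 1 group or both, and 93 of the called genes had none.

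The platform annotation listed 1 gene symbol for 23521 probe sets, several for 1814 and none for 16010. Genes came only from probe sets with 1 symbol, 22180 genes in all. For the 1082 genes with over 1 probe set, the probe set with the highest mean over the 7 arrays was used. Entrez identifiers of 21994 genes were found in a RefSeq table of the mouse genome, all with the same symbol. That table also gave RNA lengths and host genes of small RNAs, and no coordinates are printed because the array's build is not given in the sources used here.

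The test was limma (version 3.58.1, R 4.3.3), lmFit and eBayes with default settings, of blastema against uninjured digit over the 7 arrays with no covariate and no filter on dim probe sets. Two-sided p-values were adjusted by Benjamini-Hochberg over all 22180 genes, and genes under 0.05 were called. Adjusted p-values of single genes in the text come from this limma fit. A log2 fold change is the blastema mean minus the uninjured mean, with its SE from the fit. The gene lists, the tests and most of the alternative settings were fixed before the data were examined. The 37 lists name 731 members, of which 670 were measured. The other 61 were not analysed here. Lists were tested by limma camera with a preset correlation of 0.01 and, as alternatives, with an estimated correlation and by directional fry. Each was adjusted over the 37 lists. Camera compares a list with the other genes, and fry does not.

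Genes named in the text follow a fixed rule. It takes the 6 largest and 6 smallest log2 fold changes among called genes whose groups do not overlap, leaving out predicted genes, clones, olfactory and vomeronasal receptors, microRNAs and small nucleolar RNAs. It adds the 2 called members of each list with the largest absolute change, or the member with the smallest p where none passed. Sox2, Ngfr, Sox10, Osm, Osmr, Pdgfa, Pdgfra, Msx1, Msx2, Bmp4 and Mki67 were fixed by name. Other genes are said to be named after their values were seen. Several named genes have other probe sets that gave smaller changes, at lower levels, among them Rpl7, Rps19, Slc2a1, Car3 and Cox5b.

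The alternative settings fixed at that point were the replicate number as a block, a filter at the 30th percentile of level, the mean of all probe sets of a gene, an intensity trend with robust variances, array weights, scaling to the reference genes or to the array median, all probe sets, and the omission of each array. Omitting both arrays numbered 1, fitting those arrays as a block, and keeping only genes above the background proxy were added after the data were seen. Results were also compared over the 35 splits of the 7 arrays into 4 and 3.

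The limma step was tested on simulated data over the same 22180 genes, with 50 genes changed at each of 4 sizes. It recovered 36% of genes changed by 0.5 on the log2 scale, 86% at 1, 100% at 2 and 100% at 3, and 11 of its 172 calls were unchanged genes. The simulation changed 200 genes, while 2139 were called in the real data. The Benjamini-Hochberg cut therefore differs, and these rates are not the power of the real test. The camera step called the list shifted by 0.5 and 0 of the others. The simulated genes varied independently of each other, so this does not test camera on lists whose genes vary together. In the real data the estimated correlation of the mitosis list was 0.847. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.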

Results

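Gene expression was measured on 1-colour arrays in tissue from C57Bl/6 mice. Blastemas, the masses of cells that form at an amputated digit tip and rebuild it, were taken 2 weeks after amputation (n = 3) and compared with uninjured digits (n = 4). The title of the study places nerve-derived Schwann cell precursors, which act on neighbouring cells through secreted factors, at the centre of this regeneration. The comparison therefore asks how the blastema differs from the intact digit, and what it shows of Schwann cell genes, secreted factors and their receptors. Each array gave 41345 probe set levels on a log2 scale, with array medians of 5.53 to 5.58. Arrays have no read depth, and the 7 arrays limit the precision. Levels correlated at r = 0.968 to 0.982 between uninjured arrays, 0.981 to 0.986 between blastema arrays and 0.952 to 0.970 between the groups, across genes. The axis of largest variance, with 57.4% of it, parted the groups. The next axis, with 14.3%, set uninjured array 1 (-24.77) and blastema array 1 (-15.78) apart from the others (3.18 to 13.59).

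Of the genes named, those with the largest rises in the blastema included genes of bone matrix, bone resorption and collagen breakdown. Krt9, Krt2, Krt4 and Krt15, all keratin genes, had the largest falls of the genes named. Ibsp, which encodes the bone matrix protein bone sialoprotein, rose from 6.41 ± 1.29 (SD, n = 4) to 12.13 ± 0.32 (SD, n = 3), a log2 fold change of 5.73 ± 0.64 (SE) or 53.0-fold. Next came the collagenase Mmp13 (5.06 ± 0.43), the gelatinase Mmp9 (4.59 ± 0.32), the imprinted gene Mest (4.13 ± 0.21), the osteoclast proton pump subunit Atp6v0d2 (3.84 ± 0.41) and the secreted protein gene C1qtnf3 (3.80 ± 0.33). Krt9, a keratin of the foot pad epidermis, fell from 10.62 ± 1.02 (SD, n = 4) to 6.52 ± 0.37 (SD, n = 3), a log2 fold change of -4.11 ± 0.52 (SE). Krt2 (-2.69 ± 0.52), Krt4 (-2.52 ± 0.35) and Krt15 (-2.30 ± 0.48) fell too, as did Wfdc21 (-1.98 ± 0.19) and Fgfbp1 (-1.96 ± 0.34), an FGF-binding protein gene. By limma with Benjamini-Hochberg adjustment, 2139 of 22180 genes passed an adjusted p of 0.05 (9.64%), 1105 higher and 1034 lower in the blastema. At least 2-fold changes numbered 339 upward and 135 downward. In 4650 genes (20.96%) the groups did not overlap, against 5.71% expected by chance, and all 2139 called genes were among them. Scaling each array to the reference genes lowered the median fold change from -0.0054 to -0.148. It gave 720 higher and 1841 lower genes, 28.11% higher in place of 51.66%. The 8 measured reference genes had a mean log2 fold change of 0.143 and a median of 0.153. Among them Gusb itself rose (0.89, limma adjusted p = 0.0218), which adds to the shift from this scaling. Calls lost under this scaling, here and below, carry the same limit. Without uninjured array 2, 3 or 4 the higher genes numbered 682, 625 and 658 and the lower genes 505, 520 and 586. Without blastema array 2 they numbered 457 and 429, and without blastema array 3, 480 and 365, with 216 and 84 of at least 2-fold. Without both arrays numbered 1, a choice made after the data were seen, 1164 genes were higher and 1100 lower. Krt2 did not pass without uninjured array 2, 3 or 4 or blastema array 2 (adjusted p = 0.0683, 0.0683, 0.0644 and 0.0508), nor did Fgfbp1 (0.0539, 0.0529, 0.0508 and 0.0695). Krt15 passed only when uninjured array 1 was the array omitted, with adjusted p of 0.0588 to 0.105 otherwise.

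**Figure D1:**
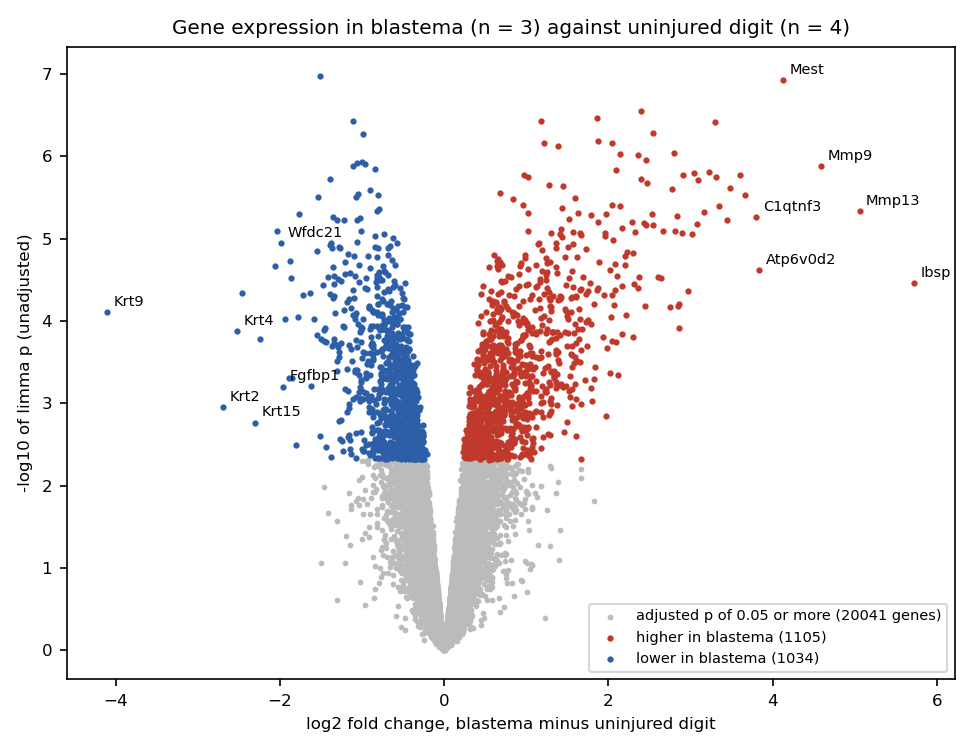
Log2 fold change of blastema (n = 3) over uninjured digit (n = 4) on the x axis against -log10 of the unadjusted limma p on the y axis, with 1 point per gene. Red points are the 1105 genes higher and blue points the 1034 genes lower at an adjusted p under 0.05, grey points are the rest, and Ibsp lies farthest right and Krt9 farthest left.

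Of 15 measured osteoblast genes, 12 rose and 0 fell, with a median log2 fold change of 2.10 (limma camera adjusted p = 1.43e-14, and adjusted p = 0.218 with an estimated correlation). Besides Ibsp, the largest rise was that of Col1a1, the main collagen chain of bone (3.48 ± 0.27 SE). The osteocyte list rose by camera (adjusted p = 0.00514, and adjusted p = 0.218 with an estimated correlation), although 8 of its 11 members did not pass. Phex (2.64 ± 0.29) and Dmp1 (2.32 ± 0.26), both genes of bone mineral control, rose, and 5 members rose when adjusted over the list alone. Of 16 osteoclast genes 11 rose, led by Mmp9 and Atp6v0d2, and 1 fell (median 0.67, camera adjusted p = 1.65e-07, and adjusted p = 0.218 with an estimated correlation). The member that fell, named after its value was seen, was the carbonic anhydrase gene Car2 (-0.68, adjusted p = 0.00826). Among 20 chondrocyte genes 6 rose and 0 fell (median 0.12, camera adjusted p = 0.0136, and adjusted p = 0.299 with an estimated correlation). Under reference gene scaling the chondrocyte median was -0.02 and the camera direction stayed upward. The cartilage genes Col11a1 (2.80 ± 0.19) and Acan (2.76 ± 0.34) rose most. Of 12 tendon and joint surface genes 1 rose, Fmod, which binds collagen (1.96 ± 0.18), and 3 fell, led by Thbs4 (-1.85 ± 0.31). The other members that fell were Angptl7 (-1.62) and Tnxb (-0.72), both named after their values were seen, and the list showed no shift by camera (median -0.38, adjusted p = 0.662). The uninjured digits differed among themselves in this list, with array means, relative to the mean of all arrays, of 0.526 and 0.466 on arrays 2 and 4, -0.395 and -0.361 on arrays 1 and 3, and -0.19 to 0.129 on the blastema arrays. Its member Prg4, named after its values were seen, lay at 8.51 ± 2.77 (SD, n = 4) in uninjured digit and 9.74 ± 0.82 (SD, n = 3) in blastema (adjusted p = 0.635). Adjusted over the list alone, 12 osteoblast, 11 osteoclast, 6 chondrocyte and 4 tendon genes rose, and 1 osteoclast and 3 tendon genes fell. Without both arrays numbered 1 the osteocyte and chondrocyte lists did not pass (camera adjusted p = 0.0517 and 0.11), and Thbs4 did not without blastema array 2 (adjusted p = 0.0508), Angptl7 without blastema array 2 or 3 (0.0647 and 0.0745) or Tnxb in 6 of the 7 omissions of 1 array (0.0572 to 0.172).

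Fibroblast matrix genes rose as a group. Of 21 measured, 18 rose and 0 fell, with a median of 1.61 (camera adjusted p = 5.53e-18, and adjusted p = 0.218 with an estimated correlation). The largest rises were those of Col12a1 (3.09 ± 0.23 SE), a fibril-associated collagen, and Col6a3 (3.08 ± 0.27), a chain of microfibrillar collagen. Of 28 matrix remodelling genes 19 rose and 0 fell, with a median of 1.21 (camera adjusted p = 5.96e-20, and adjusted p = 0.218 with an estimated correlation). Mmp13 and P4ha3, a collagen prolyl hydroxylase subunit (3.66 ± 0.29), led this list. Adjusted over the list alone, 19 fibroblast matrix genes and 21 remodelling genes rose.

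**Figure D2:**
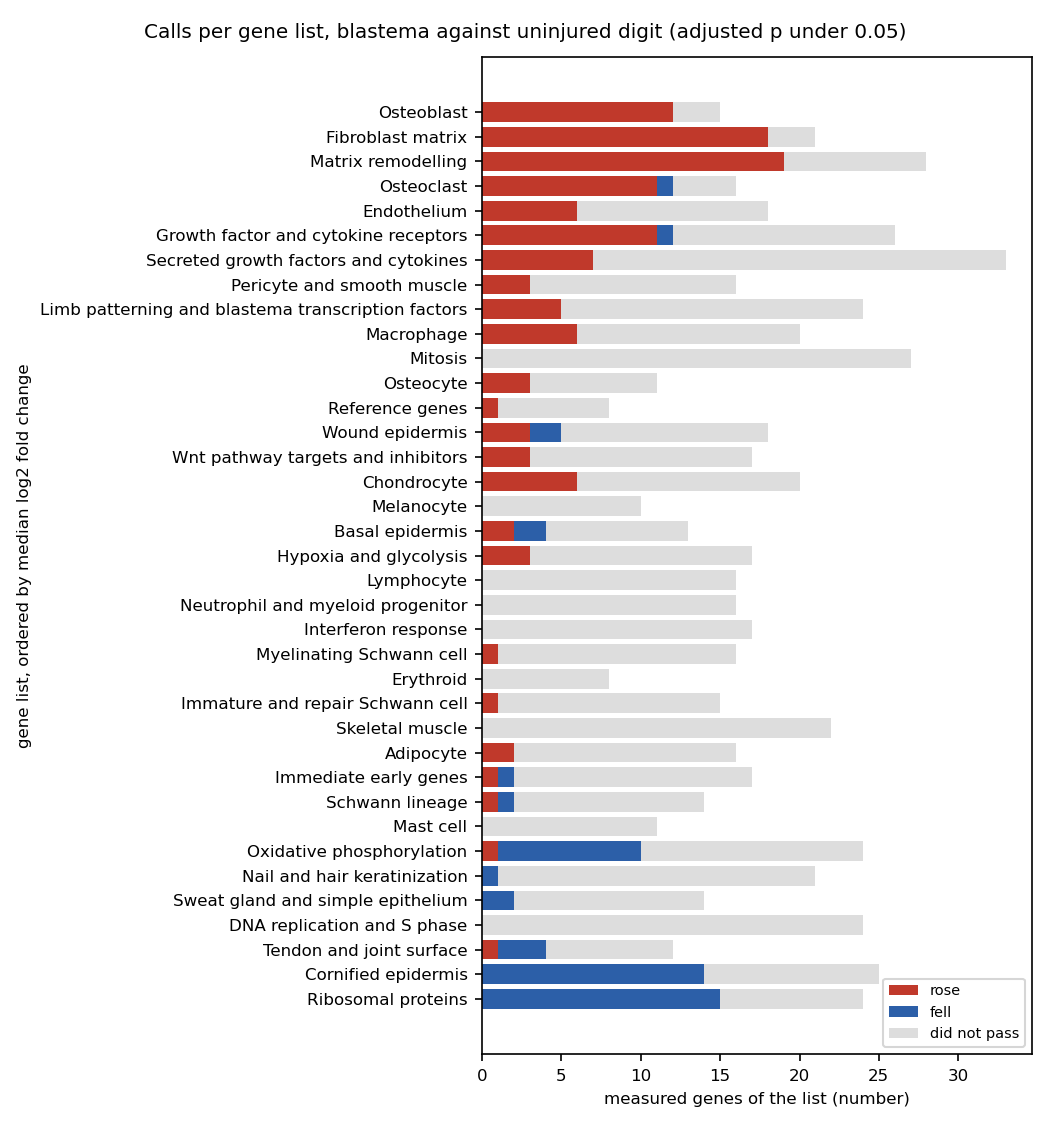
Number of measured genes per gene list on the x axis, with the 37 lists on the y axis ordered by median log2 fold change, and red for genes that rose, blue for genes that fell and grey for genes that did not pass at an adjusted p of 0.05. The osteoblast, fibroblast matrix and matrix remodelling lists at the top hold 12, 18 and 19 genes that rose, and the cornified epidermis and ribosomal protein lists at the bottom hold 14 and 15 that fell.

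Secreted growth factors and their receptors were higher in the blastema as lists. Of 33 growth factor and cytokine genes 7 rose and 0 fell, and 13 rose when adjusted over the list alone (median 0.40). The list's camera adjusted p was 1.58e-08, with adjusted p = 0.218 with an estimated correlation. Pdgfc, a PDGF ligand, rose from 6.34 ± 0.21 (SD, n = 4) to 8.50 ± 0.39 (SD, n = 3), a log2 fold change of 2.16 ± 0.19 (SE). Inhba, the activin A subunit gene (1.64 ± 0.21), and Bmp4 (1.27 ± 0.18) rose as well. Of 26 receptor genes 11 rose and 1 fell, and adjusted over the list alone 16 rose and 3 fell (median 0.44, camera adjusted p = 8.73e-06, and adjusted p = 0.3 with an estimated correlation). Pdgfrb (1.75 ± 0.20) and the oncostatin M receptor gene Osmr (1.29 ± 0.13) rose most, and Erbb2, named after its value was seen, fell (-0.32, adjusted p = 0.0323). The ligand gene Osm differed by -0.06 (95% interval -0.29 to 0.18, adjusted p = 0.781). Its means of 5.60 in uninjured digit and 5.54 in blastema lay close to the background proxy of 5.52, so low signal limits this comparison. Pdgfa differed by 0.33 (0.05 to 0.62, adjusted p = 0.138) and Pdgfra by 0.89 (0.29 to 1.48, adjusted p = 0.0764). Pdgfa passed without uninjured array 1 (adjusted p = 0.0448), and Pdgfra passed without blastema array 1 (adjusted p = 0.0262). Of 24 limb patterning and blastema transcription factor genes 5 rose and 0 fell, and 6 rose when adjusted over the list alone (median 0.30, camera adjusted p = 0.000147, and adjusted p = 0.218 with an estimated correlation). Prrx1, a marker of limb mesenchyme (1.45 ± 0.26), and the distal limb gene Hoxd13 (1.01 ± 0.22) rose. Msx2 differed by 0.31 (-0.11 to 0.73, adjusted p = 0.337), and Msx1 was not analysed here because its probe set lists several genes. Prrx1 did not pass without blastema array 2 or 3 (adjusted p = 0.0704 and 0.0746), and Hoxd13 passed only when blastema array 1 was the array omitted, with adjusted p of 0.0576 to 0.125 otherwise. Erbb2, the only member of the receptor list that fell over all genes, did not pass without uninjured array 2, 3 or 4 or blastema array 2 or 3 (0.0821, 0.0822, 0.0628, 0.0953 and 0.116).

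Schwann cell genes showed no shift as lists. Of 14 Schwann lineage genes 1 rose, the matrilin gene Matn2 (0.78 ± 0.15 SE), and 1 fell, the neuregulin receptor gene Erbb3 (-0.59 ± 0.13), with a median of -0.05 (camera adjusted p = 0.842). Of 15 genes of immature and repair Schwann cells 1 rose, the adhesion molecule gene Ncam1 (1.79 ± 0.24), with a median of -0.01, a mean of 0.11 and an upward camera direction (adjusted p = 0.641). Of 16 myelinating Schwann cell genes 1 rose, Gldn, a protein of the node of Ranvier (1.60 ± 0.19), with a median of 0.01 (camera adjusted p = 0.575). The counts adjusted over the list alone were the same for each of these lists. The camera direction of the Schwann lineage list (down) was opposite in sign to its mean of 0.02. Sox2 lay at 4.23 ± 0.40 (SD, n = 4) in uninjured digit and 3.92 ± 0.10 (SD, n = 3) in blastema, a difference of -0.31 (95% interval -0.79 to 0.16, adjusted p = 0.394). Ngfr differed by 0.26 (-0.10 to 0.62, adjusted p = 0.344) and Sox10, the transcription factor gene of the Schwann lineage, by -0.05 (-0.25 to 0.16, adjusted p = 0.795). All group means of Sox2 and the blastema mean of Sox10 (5.50) were under the background proxy of 5.52. Erbb3 passed only when blastema array 1 was the array omitted, with adjusted p of 0.0653 to 0.111 otherwise. Matn2 did not pass without uninjured array 4 or blastema array 2 or 3 (adjusted p = 0.0594, 0.0824 and 0.0877).

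No gene of either cell cycle list passed the limma test. Of 24 DNA replication genes 0 rose and 0 fell (median -0.16, camera adjusted p = 0.0421 downward, and adjusted p = 0.783 with an estimated correlation). Of 27 mitosis genes 0 rose and 0 fell (median 0.23, camera adjusted p = 0.0165 upward, and adjusted p = 0.783 with an estimated correlation, which was estimated at 0.847). The counts adjusted over the list alone were 0 as well, and at an unadjusted p under 0.05, 3 replication genes were lower and 2 mitosis genes higher. Directional fry passed neither list (adjusted p = 0.437 and 0.514), and the exact permutation p of the array means was 0.314 and 0.371. Mki67, a marker of dividing cells, differed by 0.23 (95% interval -0.52 to 0.98, adjusted p = 0.711), Plk1 by 0.72 (adjusted p = 0.0674) and Pola1 by -0.49 (adjusted p = 0.123). The mean of the mitosis list was 6.19 on uninjured array 1, 6.72 to 6.83 on the other uninjured arrays, and 6.51, 6.91 and 7.17 on the blastema arrays. Without uninjured array 1 or blastema array 2 or 3 the mitosis list did not pass camera (adjusted p = 0.394, 0.0528 and 0.464), and without uninjured array 2 or 4 or blastema array 1 the DNA replication list did not (adjusted p = 0.289, 0.0756 and 0.459), nor with the level filter (0.0817), median scaling (0.0506) or the background proxy (0.116), or without both arrays numbered 1 (0.0522). Plk1 passed without blastema array 1 (adjusted p = 0.0206).

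Genes of the outer, cornified epidermis fell, and basal epidermal genes went both ways. Of 25 cornified epidermis genes 14 fell and 0 rose, and 17 fell when adjusted over the list alone (median -0.48, camera adjusted p = 7.19e-11, and adjusted p = 0.218 with an estimated correlation). Krt2 and the cornified envelope gene Lce1a1 (-1.78 ± 0.23 SE) fell most. Krt1 (-0.17, adjusted p = 0.267) and Krt10 (-0.18, adjusted p = 0.155), the main keratins of differentiating epidermis, did not pass and are named after their values were seen. Of 13 basal epidermis genes 2 rose and 2 fell, over all genes and when adjusted over the list alone. Fermt1, a regulator of integrins (0.63 ± 0.10), and Bnc1 (0.56) rose, and Krt15 and Pkp3 (-0.61) fell, Bnc1 and Pkp3 being named after their values were seen. The basal list had a median of 0.07, a mean of -0.09 and an upward camera direction (adjusted p = 0.477), and its median was -0.07 under reference gene scaling. Of 18 wound epidermis genes 3 rose and 2 fell (median 0.15, camera adjusted p = 0.357), with 3 and 3 adjusted over the list alone. The beta-defensin gene Defb4 (0.99 ± 0.17) and the keratins Krt6a (0.55) and Krt6b (0.44) rose, and the stefins Stfa3 (-1.22 ± 0.15) and Stfa1 (-0.91) fell, Krt6a, Krt6b and Stfa1 being named after their values were seen. Of 21 nail and hair keratinization genes 1 fell, Krt35 (-1.28 ± 0.26), and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.0494, and adjusted p = 0.783 with an estimated correlation). Of 14 sweat gland genes 2 fell, the water channel gene Aqp5 (-1.11 ± 0.14) and Scgb1a1 (-0.84 ± 0.21), with the same count adjusted over the list alone (median -0.15, camera adjusted p = 0.107, fry adjusted p = 0.0321). Scgb1a1 lost its call in each omission of an array (adjusted p = 0.0551 to 0.152), Krt35 without uninjured array 2 or blastema array 2 or 3 (0.0809, 0.0969 and 0.112), Defb4 without blastema array 3 (0.0581) and Fermt1 without blastema array 2 or 3 (0.0573 and 0.0525). Over the 7 omissions of 1 array, Bnc1 lost its call in 6 (0.051 to 0.0953), Pkp3 in 4 (0.0627 to 0.0856) and Krt6b in 5 (0.0565 to 0.088), and Bnc1 and Krt6b did not pass under reference gene scaling (0.12 and 0.178). The nail and hair list did not pass without uninjured array 1 or blastema array 2 or 3 (camera adjusted p = 0.202, 0.0849 and 0.38), with the level filter (0.0834), the mean of all probe sets (0.0509), array weights (0.0517), reference gene scaling (0.177) or the background proxy (0.101), or by fry (0.366).

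**Figure D3:**
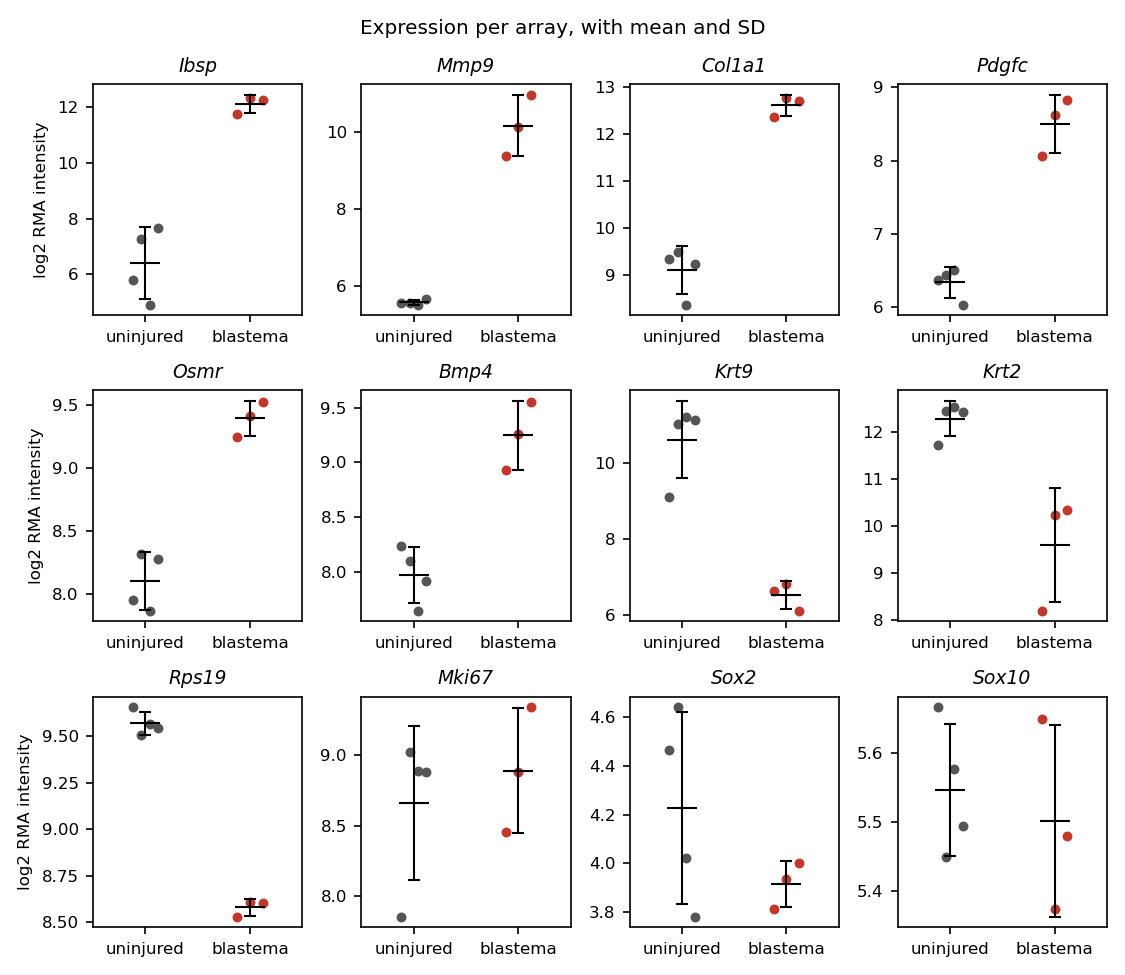
Log2 expression per array on the y axis of 12 genes, with uninjured digit (n = 4, grey) and blastema (n = 3, red) on the x axis, 1 point per array, and a line and bars for the mean and SD. The groups part in Ibsp, Mmp9, Col1a1, Pdgfc, Osmr, Bmp4, Krt9, Krt2 and Rps19 and overlap in Mki67, Sox2 and Sox10.

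Some vessel and macrophage genes were higher in the blastema. Of 18 endothelial genes 6 rose and 0 fell, and 11 rose when adjusted over the list alone (median 0.45, camera adjusted p = 5.12e-06, and adjusted p = 0.26 with an estimated correlation). The apelin receptor gene Aplnr (1.30 ± 0.21 SE) and the cadherin gene Cdh5 (1.28 ± 0.26) rose most. Of 16 pericyte and smooth muscle genes 3 rose and 0 fell, and 5 rose when adjusted over the list alone (median 0.32, camera adjusted p = 0.00278, and adjusted p = 0.362 with an estimated correlation). They were Mcam (1.32 ± 0.18), Abcc9 (1.12 ± 0.19) and Cspg4 (0.46), the last named after its value was seen. Of 20 macrophage genes 6 rose and 0 fell, and adjusted over the list alone 10 rose and 1 fell (median 0.28, camera adjusted p = 1.59e-05, and adjusted p = 0.218 with an estimated correlation). The complement gene C1qb (1.23 ± 0.20) and Gpnmb (1.17 ± 0.16) rose most. Without blastema array 2 or 3 neither Cdh5 (adjusted p = 0.0903 and 0.0716) nor Abcc9 (0.062 and 0.0539) passed, nor did Aplnr without blastema array 3 (0.0578) or Cdh5 without uninjured array 1, 3 or 4 (0.0553, 0.0728 and 0.0654). Cspg4 did not pass without uninjured array 2, 3 or 4 or blastema array 2 or 3 (0.0929 to 0.129) or under reference gene scaling (0.189).

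Other cell types gave few calls. In the neutrophil, lymphocyte, erythroid, mast cell, melanocyte, skeletal muscle and interferon lists 0 genes rose and 0 fell, over all genes and adjusted over the list alone, with camera adjusted p of 0.0993 to 0.742. Low signal may limit these counts, which was not tested. Members with a mean above the background proxy, in uninjured digit and blastema, were 2 and 4 of 16 neutrophil, 1 and 3 of 16 lymphocyte and 1 and 2 of 8 erythroid genes. For the others they were 1 and 1 of 11 mast cell, 3 and 4 of 10 melanocyte, 9 and 8 of 22 skeletal muscle and 5 and 5 of 17 interferon genes. Of 18 erythroid list members 8 were measured. At an unadjusted limma p under 0.05, 2 neutrophil, 1 lymphocyte, 1 skeletal muscle and 2 interferon genes were higher, 2 erythroid and 2 mast cell genes were lower, and 0 melanocyte genes differed. The neutrophil gene S100a8 lay at 6.19 ± 0.22 (SD, n = 4) and 8.02 ± 1.43 (SD, n = 3), a difference of 1.83 (adjusted p = 0.101), and it passed without blastema array 1 (adjusted p = 0.002). The members with the smallest p of the other lists also did not pass, namely Cd3e (0.15, adjusted p = 0.196), Tfrc (-0.55, 0.0668), Mcpt4 (-0.70, 0.0888), Pmel (-0.16, 0.291), Myoz1 (0.16, 0.199) and Cxcl10 (0.46, 0.0917). Tfrc passed without uninjured array 1 (adjusted p = 0.0196), and the mast cell list passed camera without blastema array 3 (0.035). Of 16 adipocyte genes 2 rose, Car3 (1.29 ± 0.16 SE) and the lipase gene Pnpla2 (0.40 ± 0.09), with the same count adjusted over the list alone (median -0.03, mean 0.11, camera adjusted p = 0.662 upward). Pnpla2 did not pass without uninjured array 2, 3 or 4 or blastema array 2 or 3 (adjusted p = 0.0501 to 0.0924), or under reference gene scaling (0.277).

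Many ribosomal protein genes and some genes of mitochondrial respiration fell. Of 24 ribosomal protein genes 15 fell and 0 rose, and 17 fell when adjusted over the list alone (median -0.48, camera adjusted p = 1.91e-12, and adjusted p = 0.218 with an estimated correlation). Rps19 fell from 9.57 ± 0.06 (SD, n = 4) to 8.58 ± 0.04 (SD, n = 3), and Rpl7 fell by 0.91 ± 0.10 (SE). A further Rps19 probe set had the same mean level (9.146) and fold change (-0.99) as the one used, and may not be a separate measurement. Other probe sets at lower levels gave -0.15 for Rps19 and -0.02 for Rpl7. Of 24 oxidative phosphorylation genes 9 fell and 1 rose, and adjusted over the list alone 11 fell and 1 rose (median -0.12, camera adjusted p = 0.000393, and adjusted p = 0.299 with an estimated correlation). The cytochrome oxidase genes Cox5b (-0.79 ± 0.11) and Cox5a (-0.60 ± 0.09) fell most, and Sdhc, named after its value was seen, rose (0.31, adjusted p = 0.0454). With the mean of all probe sets Cox5b differed by -0.531 and did not pass (adjusted p = 0.0672). Sdhc lost its call in 6 of the 7 omissions of 1 array (0.0568 to 0.15), under median scaling (0.0555) and under reference gene scaling, where it differed by 0.164 (0.348). Of 17 hypoxia and glycolysis genes 3 rose, the oxygen sensor gene Egln3 (0.92 ± 0.14), the glucose transporter gene Slc2a1 (0.82 ± 0.16) and, named after its value was seen, Gapdh (0.31), and 0 fell. Adjusted over the list alone 3 rose and 1 fell (median 0.05, camera adjusted p = 0.0914, fry adjusted p = 0.0321), and camera passed the list without blastema array 2 (adjusted p = 0.0203). A further Slc2a1 probe set gave 0.10. Gapdh differed by 0.179 with the mean of all probe sets (adjusted p = 0.1) and by 0.168 under reference gene scaling (0.298), and it did not pass without uninjured array 3 or blastema array 2 or 3 (0.0514, 0.0672 and 0.0742). Of 17 Wnt pathway genes 3 rose, Dkk3 (1.30 ± 0.16), Sfrp1 (0.77 ± 0.18) and, named after its value was seen, Nkd2 (0.62), and 0 fell (camera adjusted p = 0.14), with 5 and 1 adjusted over the list alone. Under reference gene scaling the Wnt list passed camera upward (adjusted p = 0.02) with a median of -0.02. Of 17 immediate early genes Ccn1 rose (0.94 ± 0.23) and Btg2 fell (-0.41 ± 0.10), also when adjusted over the list alone (median -0.04, mean 0.03, camera adjusted p = 0.867 downward). Of 8 reference genes 1 rose, Gusb (0.89 ± 0.17), also when adjusted over the list alone (median 0.15, camera adjusted p = 0.422). Sfrp1 lost its call in each omission of an array (adjusted p = 0.0562 to 0.118), and Nkd2 without uninjured array 2, 3 or 4 or blastema array 2 or 3 (0.0729 to 0.145) and under reference gene scaling (0.0816). Ccn1 passed only without blastema array 2 and Btg2 only without uninjured array 4, with adjusted p of 0.0546 to 0.165 and 0.0592 to 0.152 otherwise. Slc2a1 did not pass without uninjured array 4 or blastema array 3 (0.0609 and 0.0816), nor Gusb without uninjured array 3 or 4 or blastema array 2 or 3 (0.0628, 0.0663, 0.0892 and 0.0975).

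Of the 37 lists 18 passed limma camera with its preset correlation, 13 upward and 5 downward. With an estimated correlation 0 passed (smallest adjusted p = 0.218), and 6 had an unadjusted p under 0.05. Directional fry, which asks whether the genes of a list move on balance in a single direction, passed 17 lists, 15 of them among the 18. The array means of 15 lists gave the smallest exact permutation p that 3 arrays against 4 allow (two-sided p = 0.0286), and none passed after adjustment (adjusted p = 0.0705).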

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

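The values below were looked at because 1 uninjured array stood far from the other 3, or because they come from probe sets that no comparison above uses. In 113 values tested (76 genes named by the fixed rule or by name and 37 list means), 12 had such an array, where chance gives about 1 in 20, or 5.7. Of the 12, 8 were on uninjured array 1.

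Uninjured array 1 was lowest in Krt9 (9.10, others 11.05 to 11.21), Krt2 (11.72, others 12.43 to 12.52), Fgfbp1 (8.17, others 9.23 to 9.31) and Mki67 (7.86, others 8.88 to 9.02). It was highest in Pmel (5.94, others 5.74) and Msx2 (8.71, others 8.12 to 8.17). Its mean was highest for the neutrophil list (5.10, others 4.92 to 4.95) and lowest for the reference genes (8.79, others 8.98 to 9.01). Uninjured array 3 was lowest in Ncam1 (5.77, others 6.34 to 6.39) and C1qb (6.34, others 6.81 to 6.86). Uninjured array 4 was lowest in Cox5b (8.96, others 9.26 to 9.30) and in the mean of the basal epidermis list (8.98, others 9.09 to 9.10). In Krt9, Krt2 and Fgfbp1 the outlying value lay toward the blastema values, and in Mki67 it lay below them.

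Probe sets outside the gene test also differed between the groups when all 41345 were tested together by limma. Of 16010 probe sets with no gene listed, 224 were higher and 711 lower in the blastema. Of 1814 probe sets with several genes, 41 were higher and 107 lower.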

How the results depend on the processing

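No called list, and no called gene among those named by the fixed rule or after their values were seen, changed direction under any alternative that tested it. Of 59 called genes named by the rule, 25 kept their call under every alternative, as did 11 of 29 called genes named after their values were seen, and of 18 called lists, 13 did so under every alternative but the estimated correlation, which left 0 lists. The causes of the changes below were not tested, except that omitted arrays leave fewer samples. The alternatives with arrays numbered 1 and with the background proxy were chosen after seeing the data.

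Scaling to the reference genes, among which Gusb itself rose, gave 720 higher and 1841 lower genes, 226 of them at least 2-fold lower. All probe sets together gave 1619 lower, and the arrays numbered 1 as a block gave 1560 lower. The replicate block gave 295 higher and 304 lower genes, 176 at least 2-fold higher, and ended the call of 28 of the 59 genes and 17 of the 29, among them Krt9 (adjusted p = 0.052), Ncam1 (0.0638) and Bmp4 (0.0777). Without both arrays numbered 1, Scgb1a1 (0.229), Pnpla2 (0.0527), Sfrp1 (0.117), Slc2a1 (0.0601), Ccn1 (0.127), Btg2 (0.106), Tnxb (0.057), Bnc1 (0.0583), Krt6b (0.0606) and Sdhc (0.0578) did not pass. Nor did Scgb1a1 and Ccn1 with array weights (0.062 and 0.0545), Ccn1 under reference gene scaling (0.0684) or Scgb1a1 with the arrays numbered 1 as a block (0.0597). Whether the numbers pair the samples cannot be told from the values. Deviations of same-numbered arrays correlated at 0.286, 0.151 and -0.065. Uninjured arrays 1 and 2 correlated best with the blastema array of their own number, and uninjured array 3 with another number. Over omissions of 1 array, higher genes numbered 457 to 1286, lower genes 365 to 1009, at least 2-fold higher genes 216 to 439, at least 2-fold lower genes 84 to 155, and called lists 16 to 18.

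Some results that did not pass changed direction, by camera for lists (medians given) and by fold change for genes. The lymphocyte list did with the replicate block (-0.024) and without uninjured array 4 (omissions gave -0.024 to 0.071), the melanocyte (-0.03) and interferon (-0.073) lists with only genes above the background proxy. The Schwann lineage list did with the 30th percentile filter (-0.045), above the proxy (-0.045), without both arrays numbered 1 (-0.03) and without uninjured array 1 (-0.027, omissions -0.072 to 0.007). Reference gene scaling turned the tendon list (-0.525) and the immediate early list (-0.184), as did omission of uninjured array 3 (-0.035) or blastema array 2 (0.035) for the latter (omissions -0.102 to 0.035). Without uninjured array 1, skeletal muscle (0.004, omissions -0.051 to 0.023) and Mki67 (-0.04, omissions -0.04 to 0.446) turned, and without blastema array 2, Sox10 (0.018, omissions -0.119 to 0.018). With no detection calls, signal over background limits the dim genes, such as Sox2.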

Other observations

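The gene classes and the host gene, length and epidermal share tests below were chosen after results were seen, and the rules for reading all of these tests were set after their results. The brightness tests and the splits of the arrays were set out before their results.

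Among gene families, 17 of 44 measured collagen genes rose and 0 fell, with a median log2 fold change of 0.23 (0.09 under reference gene scaling). Of 18 late cornified envelope genes 10 fell (median -0.98) and 1 rose, Lce3b (1.11), which lost its call in 5 of the 7 omissions of 1 array (adjusted p = 0.0501 to 0.0947), and without both arrays numbered 1, 10 fell and 0 rose. Of 51 keratin-associated protein genes, which serve nail and hair, 0 passed limma (median -0.26, with 4 higher and 18 lower at an unadjusted p under 0.05), and without both arrays numbered 1, 11 fell. Over all ribosomal protein symbols, 40 of 86 fell (median -0.37) and 1 rose, the pseudogene Rps15a-ps6 (0.50), which lost its call in 6 of the 7 omissions of 1 array (adjusted p = 0.0581 to 0.103) and under reference gene scaling (0.0929). Without both arrays numbered 1, 36 fell and 0 rose. Of 71 mitochondrial ribosomal protein genes 15 fell and 0 rose (median -0.21), with 6 falling without both arrays numbered 1 and 23 under reference gene scaling.

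Small nucleolar and Cajal body RNAs, which guide the modification of other RNAs, were lower in the blastema. Of 78 measured, 48 fell and 1 rose, Snord123 (1.31, with its host Snhg18 at 1.07), with a median of -0.83, and without both arrays numbered 1, 31 fell. Another 8 genes annotated as small nucleolar RNAs under other symbols went both ways, AF357425 (1.60) and DQ267102 (0.64) rising and AF357399 falling (-1.44). Without both arrays numbered 1, 0 of these 8 rose and 0 fell, and over the 7 omissions of 1 array AF357425 lost its call in 3, DQ267102 in 4 and AF357399 in 5. The mean of the 78 on each array was 8.16 to 8.54 in uninjured digit and 7.42 to 7.62 in blastema (exact permutation p = 0.0286, the smallest possible). Of 12 other short structural RNAs, grouped by annotated type, 7 fell and 0 rose. They included the Y RNAs Rny1 (111 nucleotides, -1.30) and Rny3 (101, -1.25) and the spliceosomal Rnu12 (150, -1.04) and Rnu11 (108, -0.82). The others were the RNase P RNA Rpph1 (325, -0.89), the ribosomal n-R5s136 (121, -1.25) and Rnu3a (212, -1.44). Rnu3a is itself a small nucleolar RNA, placed here because its annotated type is snRNA. Rn7sk, of 332 nucleotides, differed by -0.14 (adjusted p = 0.245), and Terc, of 397, by -0.36 (adjusted p = 0.152), while Rprl1 and Rprl2, both of 238, differed by -0.20 and -0.51 (0.249 and 0.0789). Rny3 lost its call in 6 of the 7 omissions of 1 array (0.0628 to 0.076) and without both arrays numbered 1 (0.147). Of 478 microRNA genes 8 rose and 8 fell (median -0.02), with 5 and 24 under reference gene scaling (median -0.164) and 10 and 17 without both arrays numbered 1.

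The measured transcript levels of the host genes fell less than the small nucleolar RNAs. Transcription of the hosts was not measured, so a lower host transcription cannot be excluded. Over 63 pairs with 49 hosts, the small RNA fell more than its host in 53, by a median difference of -0.505 (sign-flip permutation p = 1e-04, the smallest these draws can give). This p treats the pairs as independent, although they share arrays and some share hosts. It measures spread across pairs and not across samples. Brightness of the probe sets does not account for the fall, since 10000 lists matched on level had medians of -0.095 to 0.034 (the central 95%) against -0.828. A loss of the shortest RNAs in extraction or labelling may contribute and cannot be told apart from regulation, since the correlation of fold change with length across these RNAs, of 48 to 248 nucleotides, was rho = -0.176 (permutation p = 0.119, bootstrap interval -0.391 to 0.057, Pearson r = -0.162). The longer box H/ACA RNAs (median 118.5 nucleotides) fell in 20 of 26, with a median of -1.074. The shorter box C/D RNAs (median 68) fell in 24 of 47, with a median of -0.734. The longest of the 78 by annotation, Scarna6 (248, -1.065) and Snord17 (221, -1.533), both named after their values were seen, fell too. The annotated lengths were not checked. Some box H/ACA entries, at 56 to 62 nucleotides, lie far below their class median, which limits the length comparisons. Within these lengths the shorter class did not fall more. A loss of all RNAs below some length would leave no such gradient, so these values do not exclude it. Of the other short RNAs of 238 nucleotides or longer, Rpph1 fell too and Rn7sk, Terc, Rprl1 and Rprl2 did not pass. A biological difference between the tissues stays open and untested.

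The fall of cornified epidermis genes (median -0.479) lies outside the -0.228 to 0.09 of lists matched on level. A lower share of epidermis alone would lower basal genes too, and 0.5 of the cornified shift of the array means (-0.643) was taken as the least fall it would give them. The array means of the basal list shifted by -0.085 (Welch 95% interval -0.222 to 0.052), above -0.322, and by -0.123 to -0.056 when each array was omitted, where 0.5 of the cornified shift was -0.339 to -0.295. By this cut, which was chosen after the results, a lower share that lowers both lists alike does not account for the fall. Basal genes went both ways (SD of their log2 fold changes 0.729), so the test cannot exclude that a lower share contributes. The explanation of the fall stays open. A different region of skin in the dissected tissue was not tested.

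The fall of ribosomal protein genes (median -0.484) also lies outside that of lists matched on level (-0.19 to 0.092). Dilution by abundant matrix transcripts was not tested, because normalization between arrays holds the median of the other genes near 0. The explanation stays open, and a change in the mix of cell types was not tested either.

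Of the 35 splits of the 7 arrays, 1, the real split, gave the full gene counts. These were 1105 higher genes, 1034 lower genes, and 339 and 135 of at least 2-fold, and the highest other split gave 0. A share of 1 in 35 is the smallest possible, so the splits go against chance without excluding it. Every other split puts blastema and uninjured arrays on the same side, so the real difference adds to its spread and lowers its counts. Directional fry passed 17 lists in the real split and 0 in the highest other, so that 1 of 35 splits gave as many, with the same limits. For lists passing camera, 2 of the 35 splits gave as many, with 18 in the real split and 18 in the split of uninjured arrays 1, 2 and 4 from the rest. That split keeps all blastema arrays together, so it carries part of the real difference. Its tie therefore does not decide whether chance gave the count.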
